A study of Homo sapiens with 6 samples.

How the data were processed

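Gene expression was measured by RNA sequencing in 6 libraries labelled as the human cell line Hep3B, with RNA extracted with Trizol and libraries made by Illumina protocols, per the labels' protocols. The series holds 1 table of 48162 genes with hg19 coordinates. Its read counts are raw whole-number counts per gene, per the file headers, and summed to between 18460506 and 24984618 per library. The FPKM values deposited beside them equal the count divided by gene length and column total, with a largest relative difference of 1.37e-07, and were not used in a test. The submitters' processing notes name CASAVA, STAR, limma and the hg19 build, without versions, roles or order. The read counter, the gene annotation and its release, the use of strand and any filter before deposit are not given in the sources used here. Reads of a gene therefore cannot be told from those of an overlapping gene, on either strand, and genes that share sequence with a pseudogene are uncertain. Of the 118 genes named from the comparisons and lists, 29 overlap another gene of at least 1 CPM by the coordinates of the table. Every gene had a name, and no column of another sample was left over.

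Libraries were grouped by the genotype and treatment labels as FIG-ROS1, untreated WT and WT with 1 µg/mL RNase7 for 1 h, with 2 libraries each. The titles of the RNase7 libraries share a letter with those of the FIG-ROS1 libraries, but their genotype label is WT, so untreated WT served as their control. The tests, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined, except where stated otherwise. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, two-sided, TMM normalisation, filterByExpr by group with a minimum count of 10 and a minimum total of 15) in a single fit of all 6 libraries with 3 residual degrees of freedom and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter kept 18158 genes. The SE of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-normalised library sizes.

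For single genes the text names, in each comparison, genes from the 12 largest rises and the 12 largest falls among genes with a symbol, past the threshold, with a mean of at least 5 CPM and with no overlap between the libraries of both groups. Where under 5 genes passed, genes came from the 10 of lowest p. ROS1, GOPC and RNASE7 were always included. For each gene list described, up to 4 members of lowest p could be named, and for changes shared by both comparisons up to 6 genes per direction. Names were taken from the table, where 24205 of 48162 gene names matched a symbol of the same Ensembl identifier. A total of 41 gene lists with 1009 genes was fixed, of which 995 were found in the table and 40 lists had at least 5 tested members. Lists were tested with camera in limma 3.58.1 (two-sided, inter-gene correlation preset at 0.01, log2 CPM with a prior count of 2, Benjamini-Hochberg over the 40 lists), and again with an estimated correlation and with fry. The intervals of ratios with 3 or fewer counts in a group are exact Clopper-Pearson intervals at 95% and, like the limit of 3 counts for a count of 0, cover counting error only.

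Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter on low counts, a minimum of 10 CPM in at least 2 libraries, a fit of only the groups compared, a minimum of 1.5-fold, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data were the removal of a smooth trend in GC content and gene length from each library, alone, with the replicate block and with each library left out, the removal of mitochondrial genome transcripts, crossed replicate numbers, and a list of squamous and basal epithelial genes. The trend was fitted with natural splines of 5 degrees of freedom to genes above a mean log2 CPM of 2 and entered as an offset. GC content came from the longest GENCODE v29 transcript of the same Ensembl identifier, available for 17526 of the tested genes (96.5%). That annotation is on another build, and none of its coordinates were used. Unchanged groups were simulated 20 times against the untreated WT libraries for the comparison of fold changes. Tables were read with Python 3.11.15 and pandas 2.3.3.

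The tests were tested on simulated data drawn from the untreated WT means and the real spreads and library sizes, with 200 changed genes among 18158. Genes were drawn independently and without a trend in GC content or length. The false calls therefore do not measure the error rate in the real libraries, where such trends were present. For FIG-ROS1 against untreated WT, 1 of 50 genes changed by 2-fold, 20 of 50 by 4-fold, 45 of 50 by 8-fold and 50 of 50 by 16-fold were recovered, with 4 false calls among 17958 unchanged genes. For RNase7 against untreated WT the recovered genes were 1, 21, 49 and 50 of 50, with 5 false calls, and for FIG-ROS1 against RNase7 they were 0, 26, 44 and 49 of 50, with 10 false calls. A GC trend was also simulated in FIG-ROS1 replicate 1 and RNase7 replicate 2, with a fixed spread for all genes in place of the real ones. For FIG-ROS1 against untreated WT, 0 of 200 genes changed by 4-fold were then recovered without the correction. With it, 195 of the 195 that had a GC value were recovered, with 9 false calls. This recovery is not one at the real spreads.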

Results

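RNA sequencing was performed on 6 libraries labelled as Hep3B, an established cell line that the labels describe as hepatocellular carcinoma. The libraries fell into 3 groups of 2. The first group was labelled as carrying a FIG-ROS1 fusion, in which the 5 prime part of GOPC (also called FIG) is joined to the receptor tyrosine kinase gene ROS1. The second was labelled wild type (WT) and untreated. The third was labelled wild type and exposed to 1 µg/mL RNase7, a secreted antimicrobial ribonuclease of the RNase A family, for 1 h. Read counts were given for 48162 genes on the hg19 build. The libraries labelled FIG-ROS1 held 19834649 and 18460506 counts, the untreated WT libraries 24855246 and 24984618, and the RNase7 libraries 20439138 and 24151185. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values are TMM-normalised CPM (counts scaled to a library of 1e6) with SD and n = 2, or log2 fold changes with their standard error (SE) from edgeR's quasi-likelihood test.

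The genes named in the design were examined first. ROS1 (ENSG00000047936, chromosome 6, 117609463 to 117747018, minus strand) was detected at 3.88 ± 0.22 CPM (SD, n = 2) in untreated WT, at 66.7 ± 16.1 CPM in the libraries labelled FIG-ROS1 and at 46.6 ± 31.6 CPM in those labelled RNase7. It was called higher than untreated WT in both groups, by 4.10 ± 0.57 (SE) on the log2 scale in FIG-ROS1 (edgeR adjusted p = 0.00927) and by 3.58 ± 0.56 in RNase7 (edgeR adjusted p = 0.0159). The single RNase7 libraries had 24.2 and 68.9 CPM, and the single FIG-ROS1 libraries 78.0 and 55.3 CPM. GOPC (ENSG00000047932, chromosome 6, 117639374 to 117923691, minus strand) was at 98.3 and 31.8 CPM in the FIG-ROS1 libraries, at 26.3 and 122 CPM in the RNase7 libraries and at 29.8 ± 1.27 CPM in untreated WT, and passed the threshold in neither comparison (edgeR adjusted p = 0.304 and 0.249). RNASE7 (ENSG00000165799, chromosome 14, 21510385 to 21512393, plus strand) was low in all 6 libraries, with 0.659 ± 0.375 CPM in untreated WT, 2.44 ± 0.33 CPM in FIG-ROS1 and 2.74 ± 0.82 CPM in RNase7. It was called higher in both groups (log2 1.88 ± 0.53 and 2.04 ± 0.53, edgeR adjusted p = 0.0453 and 0.0422). ROS1 and GOPC overlap on the same strand in the coordinates of the table, and how reads in the overlap were assigned is not given in the sources used here, so both counts are uncertain. The counts are also sums over whole genes and do not distinguish a fusion transcript from a normal one. Since ROS1 and GOPC did not separate the FIG-ROS1 libraries from the RNase7 libraries, the groups are called by their labels throughout.

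**Figure D1:**
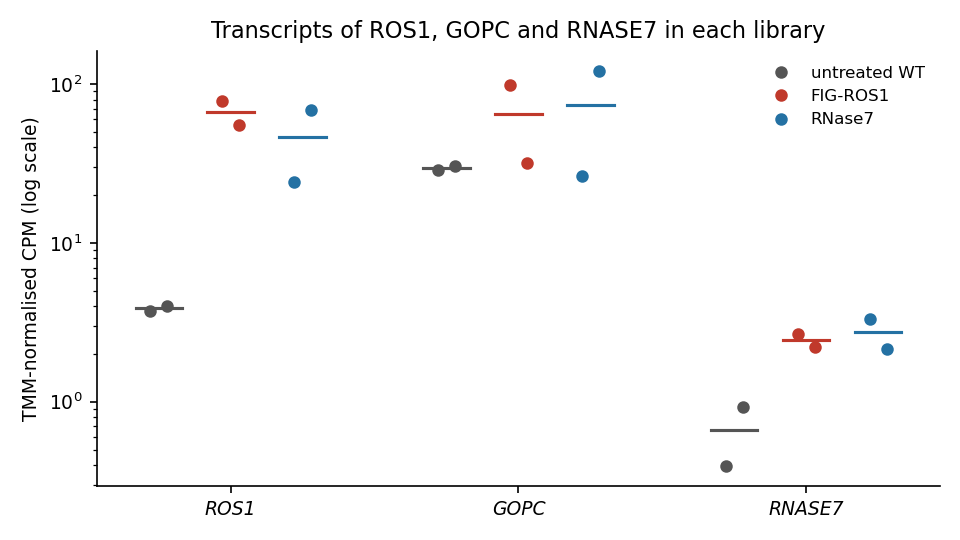
TMM-normalised CPM (log scale) of ROS1, GOPC and RNASE7 in the 6 libraries, with points for single libraries and a line for the mean of the 2 libraries of each labelled group. ROS1 is at 3.73 and 4.03 CPM in untreated WT and between 24.2 and 78.0 CPM in the other 4 libraries.

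The libraries differed in their general composition as well as in single genes. Transcripts of the mitochondrial genome took 16.1% and 13.3% of the counts in the FIG-ROS1 libraries, 10.4% and 11.6% in the RNase7 libraries, and 3.81% and 2.76% in untreated WT. The 2 libraries of each group agreed unequally, with a root mean square log2 difference over the 18158 tested genes of 0.492 in untreated WT, 0.862 in FIG-ROS1 and 1.19 in RNase7. FIG-ROS1 replicate 1 lay closer to RNase7 replicate 2 (0.459) than to FIG-ROS1 replicate 2. FIG-ROS1 replicate 1 and RNase7 replicate 2 also shared a trend with GC content. In the 2191 genes of lowest GC content, up to 39.5%, the median log2 difference from the untreated WT mean was 1.66 and 1.68 in these 2 libraries, against 0.27 in FIG-ROS1 replicate 2 and −0.25 in RNase7 replicate 1. In the 2191 genes of highest GC content the same medians were −0.89 and −0.79, against −0.31 and −0.05. Results are therefore also given after a smooth trend in GC content and length was removed from each library, a correction chosen after the data were seen.

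**Figure D2:**
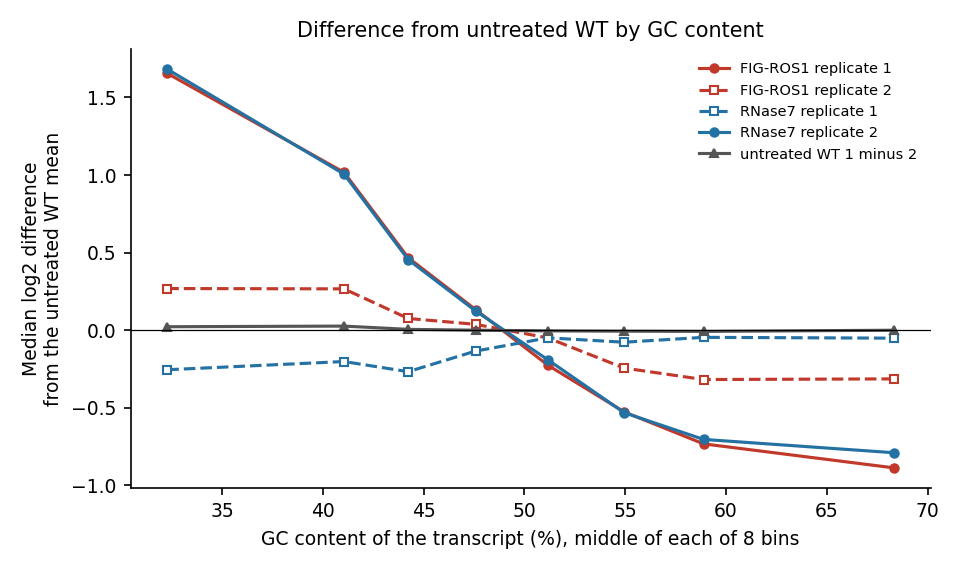
Median log2 difference of each library from the untreated WT mean (vertical axis) in 8 bins of genes by the GC content of their longest transcript (horizontal axis, %), with the difference between the 2 untreated WT libraries in grey. FIG-ROS1 replicate 1 and RNase7 replicate 2 run from 1.66 and 1.68 in the lowest bin to −0.89 and −0.79 in the highest.

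The comparison of FIG-ROS1 with untreated WT addressed how the transcriptome of cells labelled with the fusion differs at baseline. Genes for the ribosome and for DNA replication were lower in the libraries labelled FIG-ROS1, and transcripts of the mitochondrial genome and several chaperones of the endoplasmic reticulum were higher. Of 48 cytosolic ribosomal protein genes, 45 fell and 3 did not pass the test (45 also when adjusted over the list alone), with a median log2 fold change of −2.79 (camera adjusted p = 2.37e-22, and adjusted p = 0.347 with an estimated correlation). RPL27 had a log2 fold change of −3.55 ± 0.30 and RPS12 one of −3.25 ± 0.27. The list median was −2.73 in FIG-ROS1 replicate 1 and −2.85 in replicate 2, although the GC trend was far weaker in the second. The trend with gene length was alike in both, with Spearman correlations of 0.325 and 0.330 across genes. With the GC and length trend removed the list median was −2.17. Other lists differed between the 2 FIG-ROS1 libraries, with medians of −0.51 and −1.03 for the G2/M and mitosis list and of 0.21 and 0.81 for the receptor tyrosine kinases. Of 40 E2F targets and DNA replication genes, 33 fell and 7 did not pass (33 adjusted over the list alone, median −1.99, camera adjusted p = 4.62e-14, and adjusted p = 0.283 with an estimated correlation). Among them UHRF1, which recruits maintenance DNA methylation to replicated DNA, had −3.34 ± 0.28, E2F1 −3.09 ± 0.28, and the helicase subunits MCM3 and MCM6 each −2.70 (SE 0.23 and 0.25). In the G2/M and mitosis list 15 of 40 fell and none rose (19 adjusted over the list alone, median −0.68, camera adjusted p = 0.0138, and adjusted p = 0.710 with an estimated correlation). Of these, CDC20, an activator of the anaphase-promoting complex, had −2.40 ± 0.25, and the ubiquitin-conjugating enzyme UBE2C −2.03 ± 0.27.

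Mitochondrial and nuclear genes of the respiratory chain moved in opposite directions in the libraries labelled FIG-ROS1. Of 13 transcripts of the mitochondrial genome, 12 rose (12 adjusted over the list alone, median 2.13, camera adjusted p = 4.21e-07, and adjusted p = 0.400 with an estimated correlation), among them MT-ND5 by 2.76 ± 0.39 and MT-ND2 by 2.91 ± 0.46. Of 42 nuclear-encoded respiratory chain genes, 25 fell and 1 rose (31 adjusted over the list alone, median −1.497, camera adjusted p = 4.49e-07, and adjusted p = 0.347 with an estimated correlation), with COX6B1 at −3.51 ± 0.28 and NDUFB10 at −3.49 ± 0.35. Glycolytic genes were also lower, with 14 of 20 falling and 2 rising (18 adjusted over the list alone, median −1.74, camera adjusted p = 1.19e-05, and adjusted p = 0.400 with an estimated correlation). TPI1 had −3.48 ± 0.38, PGAM1 −3.16 ± 0.28 and ENO2, which overlaps LRRC23 on the same strand and is uncertain, −2.86 ± 0.25. In the hypoxia list 12 of 27 fell and 2 rose (16 adjusted over the list alone, median −0.82, camera adjusted p = 0.0283, and adjusted p = 0.347 with an estimated correlation), including the mitophagy receptor BNIP3 at −2.97 ± 0.27 and the mTORC1 inhibitor DDIT4 at −5.04 ± 0.47.

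ER chaperone and sterol synthesis genes were higher in part in the libraries labelled FIG-ROS1, but heat shock genes were not. Of these, 0 of 19 rose and 7 fell, in a list that passed as lower only with the GC and length trend removed (camera adjusted p = 0.0818, and 0.0490 with the trend removed, or adjusted p = 0.363 with an estimated correlation). Of 22 ER chaperone genes, 10 rose and 2 fell (17 changed when adjusted over the list alone, median 1.05, camera adjusted p = 0.00224, and adjusted p = 0.347 with an estimated correlation). HSPA5, the main HSP70 of the endoplasmic reticulum, had 2.97 ± 0.32 and its partner DNAJC3 2.54 ± 0.39, while the translocon subunit SEC61B had −2.93 ± 0.32. Of 25 cholesterol synthesis genes, 7 rose and 1 fell (8 adjusted over the list alone, median 0.84, camera adjusted p = 0.0283, and adjusted p = 0.347 with an estimated correlation), among them the squalene epoxidase SQLE at 1.91 ± 0.27.

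Signalling genes related to the fusion kinase changed in both directions. Among 29 receptor tyrosine kinase genes, 7 rose and 1 fell (8 adjusted over the list alone, median 0.61, camera adjusted p = 0.0291, and adjusted p = 0.710 with an estimated correlation). Besides ROS1, MET rose by 2.35 ± 0.37, and ROR1 and DDR2 by 4.16 ± 0.41 and 3.58 ± 0.48 from under 1 CPM in untreated WT. Of 32 adaptors and effectors known downstream of ROS1, 8 fell and none rose (8 adjusted over the list alone, median −0.44, camera adjusted p = 0.0481, and adjusted p = 0.400 with an estimated correlation), including the kinases MAPK3 at −2.56 ± 0.39 and MAP2K1 at −1.85 ± 0.26. The list of ERK pathway output and feedback genes did not pass, with 3 of 27 members rising and 4 falling (camera adjusted p = 0.976). In the STAT3 and acute phase list 7 of 12 fell and 1 rose (10 adjusted over the list alone, median −1.44, camera adjusted p = 0.0138, and adjusted p = 0.709 with an estimated correlation), with the feedback inhibitor SOCS3 at −2.54 ± 0.33. In the immediate early list 8 of 30 fell and 1 rose (10 adjusted over the list alone, median −0.41, camera adjusted p = 0.0499, and adjusted p = 0.710 with an estimated correlation), with IER2 at −2.10 ± 0.37 and IER3 at −1.56 ± 0.24. Neither of the last 2 lists passed once the GC and length trend was removed (camera adjusted p = 0.0780 and 0.654).

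Liver-related lists were measured on few members, since most hepatocyte genes were near 0 in every library, untreated WT included. Changes of these lists are therefore not read as changes of hepatocytes. Of 17 tested genes of hepatocyte metabolism and transport, 4 rose (4 adjusted over the list alone, median 1.02, camera adjusted p = 0.0187, and adjusted p = 0.347 with an estimated correlation). ABCC2, a canalicular export pump, rose from 6.14 ± 0.88 to 35.3 ± 2.28 CPM, and CYP2E1 from 0.991 ± 0.272 to 13.7 ± 1.56 CPM, the latter uncertain because a pseudogene overlaps it on the same strand. Of 16 hepatic transcription factor genes, 7 fell and 1 rose (9 adjusted over the list alone, median −1.15, camera adjusted p = 0.0218, and adjusted p = 0.400 with an estimated correlation), with CREB3L3 at −3.48 ± 0.44 and PPARA at −1.65 ± 0.28. Of 15 genes of PPARalpha targets and fatty acid oxidation, 3 fell (3 adjusted over the list alone, median −0.75, camera adjusted p = 0.0499, and adjusted p = 0.400 with an estimated correlation; camera adjusted p = 0.103 with the trend removed). The hepatocyte secreted protein list passed as higher only with the trend removed (camera adjusted p = 0.166, and 0.0351 with the trend removed, or adjusted p = 0.363 with an estimated correlation).

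The single genes with the largest changes included TNFRSF9, a co-stimulatory receptor of the TNF receptor family (ENSG00000049249, chromosome 1, 7979907 to 8000926, minus strand), which rose from 0.300 ± 0.009 to 26.9 and 23.1 CPM in the single libraries (log2 6.35 ± 0.40, edgeR adjusted p = 0.00785). SAMD14 rose by 5.09 ± 0.70 and CCDC166 by 6.25 ± 0.69, each overlapping an expressed gene on the other strand. CLGN, an endoplasmic reticulum chaperone (chromosome 4, 141309609 to 141349122), rose by 5.29 ± 0.92. SLITRK6 and CLEC2B had 3 counts in the untreated WT libraries together, against 948 and 504 in FIG-ROS1, a ratio of 389 (95% exact interval for counting error 133 to 1892) and of 207 (70.4 to 1007). Their FIG-ROS1 libraries differed, at 38.3 and 9.92 CPM for SLITRK6 and 22.3 and 3.06 CPM for CLEC2B. ARL6IP1, LTV1, GOLGA4, ZBTB11 and SMARCA5, with log2 rises between 5.10 and 6.18, had SE values between 1.11 and 1.56. All were higher in replicate 1 than in replicate 2, ARL6IP1 at 275 against 67.8 CPM. At the other end, DDIT4 (ENSG00000168209, chromosome 10, 74033678 to 74035794, plus strand) fell from 676 ± 52.2 to 20.6 ± 3.96 CPM (edgeR adjusted p = 0.00785). HES7, a transcriptional repressor of the Hes family, had a log2 fold change of −4.99 ± 0.46, the imprinted non-coding RNA H19 (chromosome 11, 2016406 to 2022700) −4.12 ± 0.43, LRRC20 −4.11 ± 0.69 and RPL35 −4.06 ± 0.52. The actin-binding TMSB10 had −3.98 ± 0.38, E2F2 −3.84 ± 0.39, the complex III subunit UQCR10 −3.84 ± 0.42 and the calcium-binding S100A2 −3.83 ± 0.33. POLR2L, a subunit shared by the nuclear RNA polymerases that overlaps CD151 on the other strand, had −4.51 ± 0.34. MTND2P28, RPS2P5 and PPIAP22, at 5.33, −4.16 and −3.97, are pseudogenes that share sequence with their parent genes and are uncertain.

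In this comparison 4895 of 18158 genes passed the threshold, 1977 higher and 2918 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 16 of 40 lists passed, 5 higher and 11 lower, none of them with an estimated correlation. Leaving out FIG-ROS1 replicate 1 or 2 or untreated WT replicate 1 or 2 lowered the count of genes to 3, 0, 0 and 0, and leaving out RNase7 replicate 1 or 2, which enter the shared estimate of the spread, raised it to 8172 and 8193. With the GC and length trend removed 9923 genes passed, 5697 higher and 4226 lower, and between 6413 and 11309 with each library also left out.

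**Figure D3:**
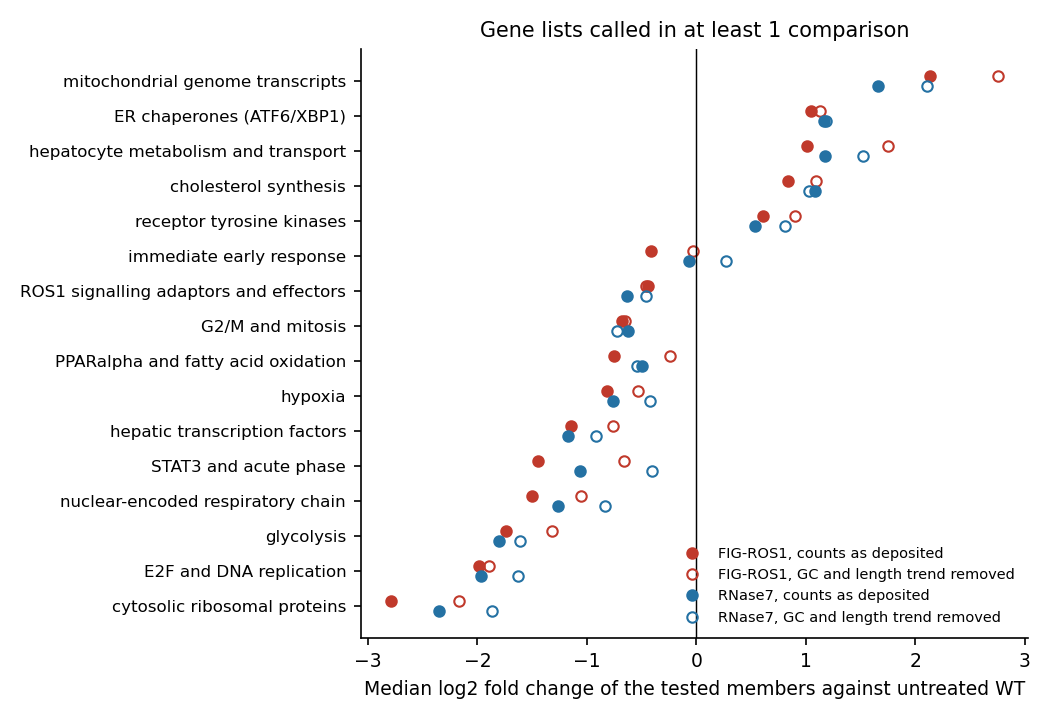
Median log2 fold change against untreated WT (horizontal axis) of the tested members of each gene list that passed the camera threshold in at least 1 of the comparisons of FIG-ROS1 (red) and RNase7 (blue) with untreated WT. Filled points use the counts as deposited and open points the values with the GC and length trend removed. Filled points run from −2.79 for cytosolic ribosomal proteins to 2.13 for mitochondrial genome transcripts with FIG-ROS1, and from −2.35 to 1.66 with RNase7. The open points of mitochondrial genome transcripts are at 2.76 with FIG-ROS1 and 2.11 with RNase7.

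The comparison of RNase7 with untreated WT was meant to address the response of cells labelled wild type to 1 h of RNase7. Its changes were close to those of FIG-ROS1 against the same untreated WT libraries (Pearson r of the log2 fold changes 0.948). Neither set of changes can therefore be assigned to RNase7 or to the fusion alone. Of 48 cytosolic ribosomal protein genes, 45 fell (45 adjusted over the list alone, median −2.35, camera adjusted p = 5.40e-23, and adjusted p = 0.328 with an estimated correlation), with RPS12 at −2.96 ± 0.26 and RPS20 at −2.78 ± 0.28. Of 40 E2F and DNA replication genes, 33 fell (34 adjusted over the list alone, median −1.97, camera adjusted p = 3.46e-15, and adjusted p = 0.253 with an estimated correlation), with MCM6 at −2.97 ± 0.26 and RRM2, a subunit of ribonucleotide reductase, at −2.85 ± 0.28. In the G2/M and mitosis list 15 of 40 fell (18 adjusted over the list alone, median −0.62, camera adjusted p = 0.00296, and adjusted p = 0.672 with an estimated correlation), with CDC20 at −1.85 ± 0.25. The median of this list was −1.18 in RNase7 replicate 1 and −0.41 in replicate 2. Of 20 glycolytic genes, 15 fell and 2 rose (17 adjusted over the list alone, median −1.81, camera adjusted p = 2.65e-06, and adjusted p = 0.409 with an estimated correlation), with TPI1 at −3.41 ± 0.38 and PGAM1 at −3.12 ± 0.28. Of 42 nuclear-encoded respiratory chain genes, 20 fell and 1 rose (26 adjusted over the list alone, median −1.26, camera adjusted p = 2.06e-06, and adjusted p = 0.328 with an estimated correlation), with NDUFB10 at −2.76 ± 0.34. Of 13 mitochondrial genome transcripts, 9 rose (12 adjusted over the list alone, median 1.66, camera adjusted p = 3.20e-06, and adjusted p = 0.428 with an estimated correlation), with MT-ND2 at 2.41 ± 0.45.

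ER chaperone and cholesterol synthesis genes were higher in part in the RNase7 libraries too. By contrast, 1 of 19 heat shock genes rose and 7 fell, in a list that passed as lower only with the GC and length trend removed (camera adjusted p = 0.0545, and 0.0145 with the trend removed, or adjusted p = 0.262 with an estimated correlation). Of 22 ER chaperone genes, 9 rose and 1 fell (14 adjusted over the list alone, median 1.16, camera adjusted p = 1.07e-04, and adjusted p = 0.328 with an estimated correlation), with HSPA5 at 2.76 ± 0.31 and SEC61B at −1.97 ± 0.31. Of 25 cholesterol synthesis genes, 6 rose and 1 fell (8 adjusted over the list alone, median 1.08, camera adjusted p = 0.0129, and adjusted p = 0.328 with an estimated correlation), with SQLE at 1.86 ± 0.27. The ROS1 adaptors and effectors had 7 of 32 members falling (7 adjusted over the list alone, median −0.64, camera adjusted p = 0.00657, and adjusted p = 0.328 with an estimated correlation), with MAPK3 at −2.70 ± 0.39. The lists of PPARalpha targets and fatty acid oxidation, hepatocyte metabolism and transport, and hepatic transcription factors had 4 of 15 falling, 2 of 17 rising and 5 of 16 falling (4, 2 and 12 adjusted over the list alone, camera adjusted p = 0.00857, 0.0106 and 0.0106, and adjusted p = 0.328 for each with an estimated correlation), with CREB3L3 at −3.34 ± 0.43 and ABCC2 at 2.26 ± 0.40. The immediate early list did not pass (camera adjusted p = 0.659), with 2 of 30 members rising, 3 falling and 0 passing when adjusted over the list alone. Of those, EGR3 and FOSB had 2.22 ± 0.51 and 1.80 ± 0.49, and IER2 −1.36 ± 0.36. The ERK output and feedback list did not pass either (camera adjusted p = 0.608, 4 of 27 rising and 2 falling), nor did the hypoxia, receptor tyrosine kinase and STAT3 lists (camera adjusted p = 0.0982, 0.103 and 0.118). With the GC and length trend removed the receptor tyrosine kinase list passed as higher with RNase7 as well (camera adjusted p = 0.0334, median 0.81, and adjusted p = 0.581 with an estimated correlation). So did the MYC and ribosome biogenesis list (camera adjusted p = 0.0232, and adjusted p = 0.329 with an estimated correlation). VEGFA, the angiogenic growth factor in the hypoxia list, rose from 119 ± 6.97 to 357 ± 19.6 CPM (log2 1.58 ± 0.23, edgeR adjusted p = 0.0141).

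The large single changes with RNase7 again included a rise of TNFRSF9, from 0.300 ± 0.009 to 17.3 ± 2.64 CPM (log2 5.82 ± 0.40, edgeR adjusted p = 0.0136), and of CCDC166 (6.09 ± 0.68), SAMD14 (4.93 ± 0.70) and CLGN (4.78 ± 0.90). IFNE, an epithelial type I interferon that overlaps a non-coding transcript on the same strand, rose by 4.91 ± 1.13. Its single RNase7 libraries were at 3.22 and 24.2 CPM. MIR17HG, the host transcript of a microRNA cluster, rose from 0.574 ± 0.377 to 24.6 ± 29.8 CPM (log2 5.41), with 3.56 and 45.7 CPM in the single libraries. SLITRK6 and CLEC2B had 1079 and 788 counts in the RNase7 libraries, a ratio to untreated WT of 345 (95% exact interval for counting error 118 to 1677) and of 252 (86.0 to 1225). Their RNase7 libraries differed, at 2.12 and 37.3 CPM for SLITRK6 and 1.44 and 27.3 CPM for CLEC2B. DDIT4 fell from 676 ± 52.2 to 40.5 ± 21.2 CPM (log2 −4.06 ± 0.45, edgeR adjusted p = 0.0136). The cell cycle transcription factor MYBL2 (chromosome 20, 42295754 to 42345136) had −3.77 ± 0.47, the histone chaperone ASF1B −3.59 ± 0.33, E2F2 −3.60 ± 0.38, the thyroid hormone receptor THRA, which overlaps 2 genes on the other strand, −3.49 ± 0.52, SAMD1 −3.45 ± 0.51 and H19 −3.45 ± 0.42. The pseudogenes RPSAP47, HMGN2P5 and PPIAP22, at −4.37, −4.04 and −3.94, are uncertain.

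With RNase7, 3877 of 18158 genes passed the threshold, 1554 higher and 2323 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 12 of 40 lists, 4 higher and 8 lower, none of them with an estimated correlation. Leaving out untreated WT replicate 1 or 2 lowered the count of genes to 0 and 0, leaving out FIG-ROS1 replicate 1 or 2 lowered it to 2288 and 2000, and leaving out RNase7 replicate 1 raised it to 7192. With the GC and length trend removed 9433 genes passed, 5364 higher and 4069 lower, and between 5622 and 10130 with each library also left out.

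The FIG-ROS1 and RNase7 libraries were then compared with each other, both by the overlap of their changes and directly. Of the genes called in each comparison with untreated WT, 3462 were shared, 1349 higher and 2113 lower in both, and 0 were called in opposite directions. For independent lists 169 and 373 shared genes were calculated, and 20 simulations of unchanged groups against the same 2 untreated WT libraries gave 0. Unchanged groups yield hardly any calls, so this 0 does not measure what the shared controls add. TNFRSF9, CCDC166, SLITRK6, CLEC2B, ARL6IP1 and LTV1 were the shared rises, and DDIT4, PPIAP22, LRRC20, E2F2 and ASF1B were among the shared falls, of largest size in both. SLITRK6, CLEC2B, ARL6IP1 and LTV1 were higher in FIG-ROS1 replicate 1 and RNase7 replicate 2, the 2 libraries that shared a GC trend. In replicates 1 and 2, ARL6IP1 was at 275 and 67.8 CPM in FIG-ROS1 and 11.2 and 225 CPM in RNase7. LTV1 was at 41.2 and 10.7, and at 3.17 and 55.7 CPM. TNFRSF9 differed less, at 26.9 and 23.1, and at 15.4 and 19.2 CPM, and CCDC166 differed the other way. Across the 18158 genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of 0.948 and a Spearman correlation of 0.947, against a simulated r of 0.497 for unchanged groups. Their covariance was 1.84, against a simulated 0.169, a difference of 1.67. With a separate single untreated WT library for each comparison, r was 0.907 and 0.872. The shared calls could not be tested again with 2 separate control libraries for each comparison, so part of their excess may come from the shared controls. Without RNase7 replicate 2, r was 0.802. The shared count was 3, 0, 0 and 0 without FIG-ROS1 replicate 1 or 2 or untreated WT replicate 1 or 2, 6206 without RNase7 replicate 1, and 8379 with the GC and length trend removed. The lists that passed in one comparison with untreated WT were not all called in the other, and that difference is tested by the direct comparison.

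In the direct comparison of FIG-ROS1 with RNase7, 0 of 18158 genes passed the threshold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 484 genes at an unadjusted p under 0.05. By DESeq2 1 gene passed and by limma-voom 0. Without RNase7 replicate 2 the count stayed 0, with 3379 genes at an unadjusted p under 0.05, and it was 263 (128 higher and 135 lower in FIG-ROS1) when the GC and length trend was also removed. The gene called by DESeq2 was the long non-coding RP11-329L6.1 (chromosome 17, 62223330 to 62223836), at 1.39 and 1.42 CPM in FIG-ROS1 and 9.62 and 9.08 CPM in RNase7 (edgeR log2 −2.73 ± 0.39). Among the 10 genes of lowest p, none of which passed with edgeR, VEGFA had a log2 difference of −1.03 ± 0.22, with 174 ± 6.81 CPM in FIG-ROS1 and 357 ± 19.6 CPM in RNase7. NFATC2, a calcium-regulated transcription factor, had 1.63 ± 0.31, with 20.5 ± 2.04 CPM in FIG-ROS1 and 6.60 ± 0.09 CPM in RNase7. The small nucleolar RNA host gene SNHG7 had −1.25 ± 0.25, C9orf142 −1.35 ± 0.28 and POLR2L −1.42 ± 0.30. ROS1 differed by 0.52 ± 0.50, GOPC by −0.19 ± 0.78 and RNASE7 by −0.16 ± 0.50, none past the threshold. In single libraries ROS1 was at 78.0 and 55.3 CPM in FIG-ROS1 and at 24.2 and 68.9 CPM in RNase7. Its difference therefore rests on RNase7 replicate 1. Of 40 lists, 11 differed by camera, 3 higher and 8 lower in FIG-ROS1, although none of their members passed and none of the lists did with an estimated correlation. Mitochondrial genome transcripts were higher in FIG-ROS1 (median 0.52) and cytosolic ribosomal protein and immediate early genes lower (medians −0.38 and −0.39, camera adjusted p = 6.01e-07 for each, and adjusted p = 0.559, 0.570 and 0.559 with an estimated correlation). The STAT3 and acute phase list had a median of −0.55 and the replication-dependent histones −0.50 (camera adjusted p = 2.21e-05 and 4.54e-05, and adjusted p = 0.559 for each with an estimated correlation). With the GC and length trend removed the histone list no longer passed (camera adjusted p = 0.309, median −0.15), nor did the nuclear-encoded respiratory chain (camera adjusted p = 0.0559). The STAT3 median was then −0.33. The epithelial junction and keratin list and the interferon-stimulated genes passed as higher in FIG-ROS1 only with the trend removed (camera adjusted p = 0.0120 for each, and adjusted p = 0.514 for each with an estimated correlation). Receptor tyrosine kinase and hypoxia genes had medians of 0.21 and −0.15 (camera adjusted p = 0.0153 and 0.0226, and adjusted p = 0.756 and 0.559 with an estimated correlation). Against untreated WT the receptor tyrosine kinase medians of single libraries overlapped, at 0.21 and 0.81 in FIG-ROS1 and 0.82 and 0.07 in RNase7. So did those of the STAT3 list, at −1.84 and −1.22, against −0.80 and −1.36. The mitochondrial genome, ribosomal protein, immediate early, nuclear-encoded respiratory chain and hypoxia medians did not overlap. Ribosomal protein medians came close, at −2.73 in FIG-ROS1 replicate 1 and −2.70 in RNase7 replicate 2.

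Levels of cell type markers were given by the same libraries. The list of 39 hepatocyte secreted proteins had a median between 0 and 0.0992 CPM in the 6 libraries, and 9 of its genes averaged at least 1 CPM. ALB had at most 8 counts in a library and AFP, the fetal albumin-like protein that is a marker of hepatocellular carcinoma, at most 2. GPC3 and TTR had 0 counts in all 6 libraries, which allows up to 0.108 to 0.170 CPM in a library (3 counts, counting error only). The fibroblast, endothelial and leukocyte lists had medians of at most 0.545, 0.198 and 0.0360 CPM. The keratin genes KRT5 and KRT14, which basal cells of squamous epithelia express, were at 10564 ± 765 and 1303 ± 94.5 CPM in untreated WT, at 1701 ± 185 and 318 ± 53.8 CPM in FIG-ROS1, and at 2038 ± 666 and 322 ± 148 CPM in RNase7.

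**Figure D4:**
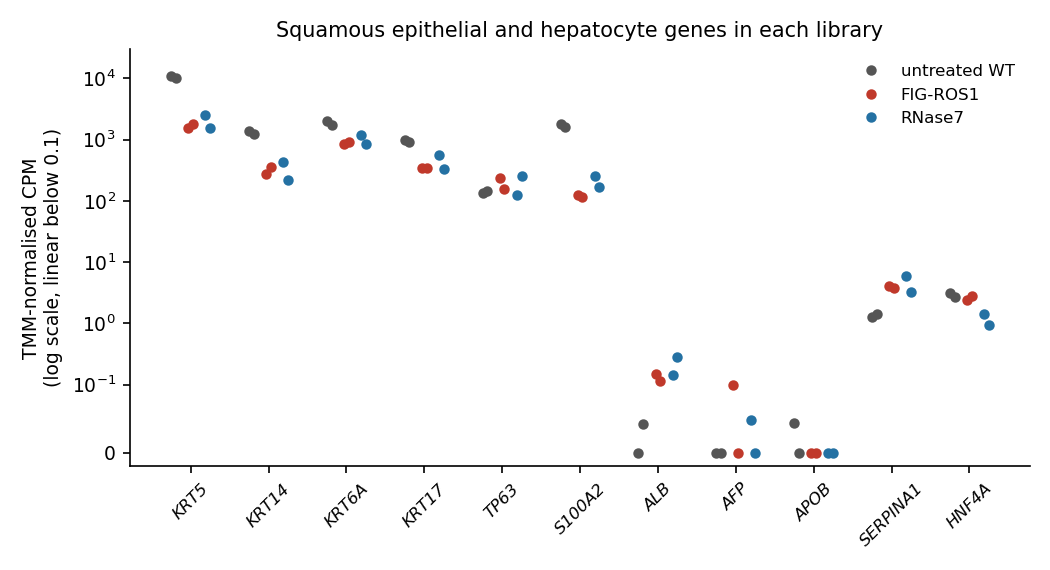
TMM-normalised CPM (vertical axis, log scale, linear below 0.1) of genes of squamous and basal epithelium (KRT5, KRT14, KRT6A, KRT17, TP63, S100A2) and of hepatocytes (ALB, AFP, APOB, SERPINA1, HNF4A) in the 6 libraries, coloured by labelled group. KRT5 averages 10564 CPM in untreated WT, and ALB has at most 8 counts in a library.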

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

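Alternatives using GC content and length, mitochondrial genome transcripts, crossed numbers or 2 choices together were chosen after the data were seen. Counts are given in the order FIG-ROS1, RNase7. The counts of genes against untreated WT (main values 4895 and 3877) moved by over 1.5 times with at least 10 CPM in at least 2 libraries (3183 and 2522), with the trend removed (9923 and 9433), and with the trend removed and the replicate block (8500 and 7931). With no filter RNase7 gave 6280 genes, and with only the 2 groups compared FIG-ROS1 gave 8109. With each library left out the counts ran from 0 to 8193 and from 0 to 7192, and with the trend also removed from 6413 to 11309 and from 5622 to 10130. Among the latter, FIG-ROS1 gave 7487 without its replicate 2 and 11236 without RNase7 replicate 2, and RNase7 gave 8800 and 8756 without FIG-ROS1 replicate 1 and 2, 5911 without untreated WT replicate 2 and 8450 without its own replicate 2. In leave-one-out fits that leave a group with 1 library, that library is assumed to vary like those of the other groups. DESeq2, limma-voom, DESeq2 size factors, a minimum of 1.5-fold and the removal of mitochondrial transcripts stayed within 1.5 times, and DESeq2 gave 2815 higher and 2712 lower genes for RNase7. Removing the trend moved the median log2 fold change of all genes from 0.11 to 0.22 and from 0.09 to 0.21. The count between FIG-ROS1 and RNase7, 0, was 1 with DESeq2 and 1 with no filter (RP11-329L6.1 in both), stayed 0 with each library left out, and was 263 without RNase7 replicate 2 when the trend was removed. The correlation of fold changes ran from 0.802 to 0.946 with each library left out. Genes called in both comparisons (3462) were 5499 with no filter, 2299 with at least 10 CPM, 8379 with the trend removed, and 0 to 6206 with each library left out. With fry in place of camera 20 and 16 lists passed, among them 13 of the 16 and 11 of the 12 called by camera. The G2/M and mitosis list did not pass in either comparison (fry adjusted p = 0.194 and 0.205). Nor did the receptor tyrosine kinase and immediate early lists for FIG-ROS1 (fry adjusted p = 0.102 and 0.0899). The list counts, 16 and 12, were 0 and 0 with an estimated correlation, and FIG-ROS1 gave 10 lists with at least 10 CPM. With each library left out they ran from 9 to 17 and from 9 to 16. With the replicate number as a block the counts of genes were 1017 for FIG-ROS1, 0 for RNase7 and 0 in both. The labels do not say whether the numbers pair libraries. Same-numbered FIG-ROS1 and RNase7 libraries deviated in opposite directions (r = −0.768 across genes, and −0.431 with the trend removed). These correlations alone do not decide whether libraries were paired. Crossed numbers gave 7461 and 6410 genes, and 0 between FIG-ROS1 and RNase7. Of single named genes, 7 values changed sign, none of them called: GOPC with RNase7 was −0.18 without RNase7 replicate 2, GOPC between FIG-ROS1 and RNase7 was 0.37 without FIG-ROS1 replicate 2 and 1.31 without RNase7 replicate 2, ROS1 between them was −0.0305 without RNase7 replicate 1, and RNASE7 between them was 0.0660 with the trend removed, 0.0649 with the block as well, and 0.20 without RNase7 replicate 1. Of the named values with each library left out, 537 kept their call or lack of one and 510 lost it with the same direction. Values of the fixed genes that moved without a change of sign included GOPC with RNase7 without RNase7 replicate 1 (2.04), GOPC between FIG-ROS1 and RNase7 without FIG-ROS1 replicate 1 (−1.20), and RNASE7 between them without RNase7 replicate 2 (−0.43). GOPC with FIG-ROS1 also depended on the library, at a log2 difference from the untreated WT mean of 1.72 in replicate 1 and 0.095 in replicate 2. ROS1 between the groups depended on the RNase7 libraries, at 24.2 CPM in replicate 1 and 68.9 CPM in replicate 2.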

Other observations

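Further lists held strong single changes without passing as lists. Among YAP/TEAD targets the matricellular CYR61 was higher by 2.72 ± 0.27 (SE, log2) in FIG-ROS1 and 2.65 ± 0.27 in RNase7, and F3, the tissue factor that starts coagulation, by 3.38 ± 0.41 and 3.77 ± 0.42 (6 and 7 of 20 rose and 3 and 3 fell, camera adjusted p = 0.103 and 0.156). Among TGF-beta targets the inhibitors of differentiation ID1 and ID3 had −3.55 ± 0.28 and −3.79 ± 0.33 in FIG-ROS1 and −2.54 ± 0.27 and −3.02 ± 0.31 in RNase7 (camera adjusted p = 0.760 and 0.578). Interferon-stimulated genes went both ways, with RSAD2 at 3.33 ± 0.37 and ISG15 at −2.59 ± 0.31 in FIG-ROS1 and 2.82 ± 0.36 and −2.15 ± 0.30 in RNase7 (camera adjusted p = 0.339 and 0.679). The metal-binding MT2A and the ferritin subunit FTL fell in both groups, by 3.39 and 3.29 in FIG-ROS1 and by 2.18 and 2.87 in RNase7, in a list of NRF2 targets and metallothioneins that did not pass (camera adjusted p = 0.0818 and 0.248). TNFAIP3, a feedback inhibitor of NF-kB, was at 7.18 ± 0.242 CPM (SD, n = 2) in untreated WT, 28.7 ± 1.55 CPM in FIG-ROS1 and 39.6 ± 5.84 CPM in RNase7, in a list that did not pass (camera adjusted p = 0.556 and 0.725).

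Of the tests that follow, those of GC content and length on the crossed pairs, of a batch of the untreated WT pair and of cell identity were chosen only after the result was seen. The first pattern is that FIG-ROS1 replicate 1 resembled RNase7 replicate 2 (root mean square log2 difference 0.459) more than its own replicate (0.862). GC content and length accounted for 76.7% of the variance of FIG-ROS1 replicate 1 minus 2 and 75.7% of that of RNase7 replicate 2 minus 1, against 5.29% between the untreated WT libraries, so a candidate explanation is a bias of fragment or amplification kind that differed between single libraries. An exchange of a FIG-ROS1 and an RNase7 library cannot be told apart from it: GOPC, of which a fusion transcript carries a part, lay above 93.7% and 85.3% of genes of like GC content and length in these differences, which falls between the bounds set for the test, and ROS1 above only 47% and 75.3%, which gives no support to an exchange. With the trend removed the crossed pair FIG-ROS1 replicate 1 and RNase7 replicate 2 stayed closer, at 0.447, than the FIG-ROS1 pair, at 0.557, but FIG-ROS1 replicate 2 and RNase7 replicate 1, at 0.720 before, were at 0.644, further apart than the FIG-ROS1 pair and closer than the RNase7 pair, at 0.704. No biological explanation of this pattern was tested.

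The second pattern is that both groups differed from untreated WT in the same direction, ROS1 included. The tables argue against a smooth trend in GC content and length as the whole cause. Of 3362 shared calls with a GC value, 94.3% kept call and direction with the trend removed. That fit called 8379 of 17526 genes in both comparisons, so a call was easily kept. The median size of the shared calls went only from 2.08 to 1.74 in FIG-ROS1 and from 1.92 to 1.69 in RNase7. The covariance of 1.84 lay far above the highest simulated value, 0.178, which argues against the gene-wise spread of the shared controls as the whole cause. The simulation held no systematic offset of the untreated WT pair, so it cannot test one. Without mitochondrial genome transcripts 4496 of the 4895 FIG-ROS1 calls remained. The TMM scaling of the main fit already limits the weight of such abundant transcripts, so this does not test them as a cause. Another culture or library batch of the untreated WT pair stays open, since the labels give no batch. With the trend removed the 4 other libraries differed from untreated WT by 1.43 on average and from each other by 0.622. That would follow a batch difference or a shared response to the fusion and to RNase7. It would also follow if the RNase7 libraries came from the same cells as the FIG-ROS1 libraries, with which their titles share a letter. Whether their WT label is right was not tested. The biological explanation, a signalling response common to the fusion kinase and to RNase7, was not tested apart from a batch or a wrong label. In the RNase7 libraries it would have to act within 1 h. In that time the ribosomal protein list would reach a median log2 of −2.35 and KRT5 would go from 10564 to 2038 CPM. The immediate early list did not pass in that comparison (camera adjusted p = 0.659). How fast these transcripts can be lost was not measured. A rise of ROS1 transcripts in the RNase7 libraries, above 99.3% and 98.7% of genes of like GC content and length, is a value that a reader may want to follow up with a measurement of the fusion junction.

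The third pattern is that hepatocyte genes were near 0 in all 6 libraries, although the labels name a hepatocellular carcinoma line, while genes of squamous and basal epithelium were abundant. The 23 genes of the squamous and basal list, chosen after the data were seen, all averaged at least 1 CPM, and their median was between 336 and 828 CPM in a library. A mixture of Hep3B with other cells would leave hepatocyte transcripts, whose list median was at most 0.0992 CPM, and a loss with the fusion or the treatment would leave them in untreated WT, where it was at most 0.0420 CPM, so the tables argue against both. Libraries made from cells other than the labelled line would also show these values, with a lowest squamous median of 336 CPM. This is a hypothesis found and tested on the same data, although the hepatocyte list was fixed before they were examined.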
